A study of Oryza sativa with 4 samples.

How the data were processed

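RNA from rice flag leaves was labelled with Cy3 and hybridised to 4 one-colour Agilent arrays, 2 untreated and 2 from plants given carbon nanoparticles, per the labels. Spot intensity was extracted with Agilent Feature Extraction 11.5.1.1, per the file headers, which give the processed signal after background subtraction and spatial detrending. The deposited value table holds log2 values. Set against the scanner files, each of its columns was the log2 of the processed signal, raised to at least 1, minus the array's 75th percentile, so its scale and direction are known and it is not centred per gene. Its column medians were -3.76 and -3.85 for the control and -3.37 and -3.42 for the treated arrays, and 13.7% of the signals of control replicate 1 lay at its floor. No probe was saturated. The genome build is not given in the sources used here, and no coordinates are printed.

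Values were log2 of the processed signal minus each array's 75th percentile. Control spots were left out, and spots with an outlier flag were set to missing. A probe was kept if it was well above background on both arrays of at least 1 group, a flag for which the headers give a multiplier of 13. This kept 34187 of 59293 probes. Genes are rice locus identifiers from the files' own annotation, read from the systematic name for 53257 probes and from the probe name for 6036. None of the 1043 RefSeq accessions in the files matched the reference table of assembly ASM3414082v1. Each gene was represented by its brightest kept probe. Levels of different probes were not compared.

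Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, 2 residual degrees of freedom). The 43 gene lists were fixed before the data were examined, with 147 of 148 members named by locus on the array, and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of these, 7 were called higher and 7 lower. None was called with an estimated correlation, where the lowest adjusted p was 0.633. That estimate rests on 2 residual degrees of freedom. Its lowest unadjusted p over the 43 lists was 0.0416, and the floral organ identity list gave 0.130 at a median log2 difference of 6.88. The camera test with an estimated correlation thus had little power here, and missing it decides little. The fry test, which does not compare a list with other genes, called 14 lists, of which 10 were among those called by camera. It did not call the circadian clock, chlorophyll breakdown, auxin response and cytosolic ribosomal protein lists (adjusted p = 0.0811, 0.0723, 0.0508 and 0.510). It called the lists of yield and architecture, NAC factors, disease resistance proteins and late embryogenesis abundant proteins (0.0367, 0.0357, 0.0244 and 0.0244), which camera did not. Also fixed beforehand was the rule for named genes. It takes the 12 largest positive and 12 largest negative log2 differences among called genes with separated groups and a functional description, up to 4 members per list with the smallest p and any a statement needs, and 6 flowering genes whatever their values, of which 1 is not reported here. The 4 largest each way above background on all arrays were added after seeing the values.

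The fit was tested on simulated arrays of 22090 genes for this comparison. With 200 genes changed and the spread of each gene drawn from the fitted prior, median sizes of 1.03, 2.07 and 4.06 were recovered for true log2 changes of 1, 2 and 4, but 0 of 67, 0 of 67 and 0 of 66 genes passed the adjusted threshold. Drawing from the sample variances also gave 0 calls. Drawing from the shrunken variances gave 0, 12 and 64, but it understates the differences in spread between genes, with prior degrees of freedom of 5.88 against 2.88 on the real arrays and 2.94 in the first simulation. In a simulation added after these results, with 6378 genes changed, close to the 6380 called, 9.08%, 68.6% and 95.8% of changes of 2-fold, 4-fold and 16-fold passed, and 3.53% of the calls were false. Calls at this number of arrays thus rest on many genes changing at once. The list test called the list of raised genes and 0 of 40 random lists. The simulated genes varied independently, so this cannot tell whether the preset correlation suits lists of genes that vary together.

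All 4 arrays lay on 1 slide. Control replicate 1 was scanned apart from the others, at a detector voltage of 434.2 against 475.04. Alternatives were other background corrections, scalings, filters and probe rules, the value table, other variance models, a replicate block and leaving out each array. A scan block was added after seeing the data.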

Results

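Messenger RNA levels were measured in samples labelled as flag leaves of Swarna (MTU7029), a cultivated rice, on 4 one-colour arrays. The flag leaf is the last leaf below the panicle, and all leaves were described as taken in the same light on the day the panicle had fully emerged. A pair of arrays carried RNA from untreated plants, named control replicates 1 and 2. The other pair carried RNA from plants given carbon nanoparticles in the pot soil, in 4 doses of 80 mg at days 45, 60, 75 and 90. The arrays held 59293 rice probes, of which 58.6% and 54.1% were well above background on the control arrays and 56.4% and 55.1% on the treated arrays. The number of arrays limits the precision of every value, and the replicates were not stated to be separate plants, so p-values measure only the spread between these samples.

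The comparison asked which transcripts differed between samples labelled as flag leaves with and without carbon nanoparticle treatment. Floral organ identity genes were higher and many photosynthesis genes lower on the treated arrays. The treated samples may have held panicle or flower tissue, which these data cannot tell apart from a response of leaf cells to treatment. Of the 12 genes on the list of floral organ identity, 11 rose, among them the MADS-box genes OsMADS6 (at least 887-fold), OsMADS7 (at least 575-fold) and OsMADS8 (at least 213-fold). These limits allow for background and not for the spread between arrays. With 1 array left out they ran from 604-fold to 1302-fold, 409-fold to 810-fold and 147-fold to 309-fold. Of the 10 Calvin cycle genes tested, 8 fell and none rose, and of the 49 photosystem and light harvesting genes 25 fell and 1 rose. Lists of cell wall expansion, class III peroxidases, phenylpropanoid enzymes, cell cycle and histones, auxin response and pollen were higher than other genes. The list test used a preset correlation. None of these list calls held with an estimated correlation (lowest adjusted p = 0.633), a test with little power at 2 residual degrees of freedom. The auxin median was -0.14 under spike-in scaling, which moved all genes alike, or 0.81 relative to all genes.

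Of 22111 genes tested with limma at a Benjamini-Hochberg adjusted p under 0.05, 3810 were higher and 2570 lower with treatment. Both treated arrays lay above both control arrays for 3808 of the genes called higher and below both for all 2570 called lower. Over all genes tested, 67.9% were separated in this way in either direction, against 33.3% by chance. Neither count is independent support for the calls. A call with 2 arrays per group nearly requires separation, genes vary together, and the filter keeps probes detected on both arrays of a group. Arrays of the same group correlated across genes at 0.946 for the controls and 0.955 for the treated pair, and arrays of different groups at 0.649 to 0.700, where genes are not independent replicates. At an unadjusted p under 0.05 and a difference of at least 2-fold, 4830 genes were higher and 3505 lower. Of the called genes, 2693 were higher and 1563 lower by at least 4-fold.

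Control replicate 1 was scanned apart from the other 3 arrays, which shared a slide with it. A fit with the scan as a block was chosen after seeing the data. Control replicate 1 was the only array of its scan, so that fit sets control replicate 2 alone against both treated arrays. This is the same contrast as the comparison within the shared scan, so they are not separate checks. The median log2 difference of the floral organ identity list was 6.35 in that contrast. Higher calls made up 59.7% of all calls, but 43.9% with scaling on the array median and 26.9% with scaling on the spike-in probes. Without carbon nanoparticle replicate 1 the lower calls numbered 1383, and without replicate 2 the calls numbered 2163 higher and 1006 lower.

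For a gene well above background on neither array of a group, the fold is a lower bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value well above background. The 12 genes with the largest rises included the GDSL lipase genes Os04g0507700, at least 1748-fold higher, and Os05g0419800, whose log2 difference was 10.62 ± 0.41 (SE, n = 2 per group, adjusted p = 0.00169). The lipid transfer protein genes Os11g0114900 and Os01g0691300 were at least 1496-fold and 676-fold higher. A gene described as similar to OSH1, a homeobox gene of the shoot meristem (Os03g0727000), was at least 546-fold higher. The acid phosphatase gene Os05g0190500, the chitinase gene Os05g0399700, the pectin lyase fold gene Os01g0201600, the cytochrome P450 gene Os06g0680700 and the bindin-like gene Os01g0814100 were at least 532-fold, 710-fold, 384-fold, 730-fold and 255-fold higher. The limit of Os06g0680700 was 455-fold without control replicate 1 and 1172-fold without control replicate 2. OsMADS6 and OsMADS7 completed this set.

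The 12 largest falls, ranked on fitted values that include signals below background, included the thaumatin gene Os12g0569500, a pathogenesis-related family member, at least 327-fold lower. The early light-inducible protein gene Os07g0178800, of a family that protects chloroplasts in strong light, was at least 266-fold lower, a limit that rested on unequal control arrays, as it was 76.3-fold without control replicate 1 and 927-fold without control replicate 2 (SE of the log2 difference 1.25). The receptor kinase genes Os07g0628900 and Os06g0142500 (wall-associated) were at least 253-fold and 196-fold lower. An amino acid transporter gene (Os01g0945300), an alpha/beta hydrolase gene (Os09g0460500), a steroid dehydrogenase gene (Os07g0162100), a leucoanthocyanidin dioxygenase gene (Os06g0176850), an aldolase gene (Os12g0169600) and a peroxidase gene (Os02g0240300) were at least 232-fold, 204-fold, 180-fold, 144-fold, 108-fold and 92.2-fold lower. Without control replicates 1 and 2 in turn, the limits were 521-fold and 103-fold for Os01g0945300, 85.0-fold and 383-fold for Os07g0162100, and 250-fold and 33.9-fold for Os02g0240300. The class 3 lipase gene Os04g0657500 fell by 9.03 ± 0.44 on the log2 scale. It was well above background on only 1 treated array, so this fitted size includes a signal near background and is not a bound. The MtN3 transporter gene Os05g0426000 fell by 8.45 ± 0.49 (SE, adjusted p = 0.00184).

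Because those ranks include values near background, the 4 largest differences each way among genes well above background on all 4 arrays were added after the values were seen. Besides Os05g0419800, the rises were 9.12 ± 0.31 for the Bet v I gene Os04g0465600, 8.85 ± 0.50 for the cytochrome P450 86A1-like gene Os01g0854800 and 8.56 ± 0.42 for the stress-responsive barrel gene Os11g0150400 (log2, SE). Besides Os05g0426000, the glutathione S-transferase gene Os10g0530500 fell by 7.51 ± 0.49, the peroxisome biogenesis gene Os04g0534600 fell by 7.06 ± 0.78 and the CCT domain gene Os02g0178100 fell by 6.92 ± 0.33.

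**Figure D1:**
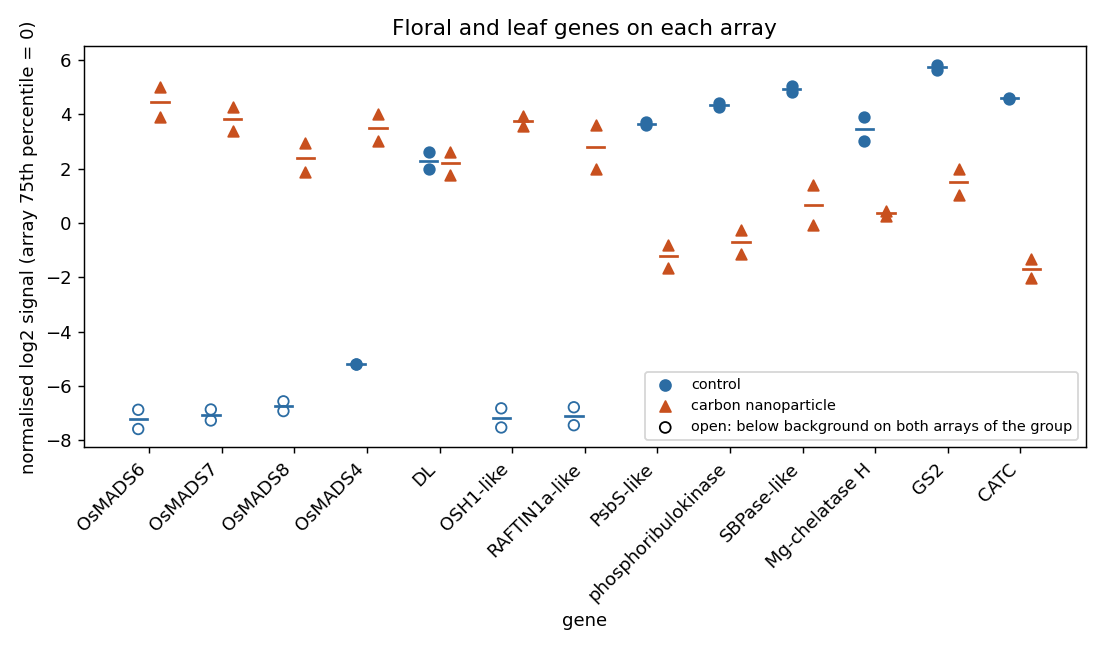
Normalised log2 signal (y axis, 0 at each array's 75th percentile) of 13 genes (x axis) on the control arrays (circles) and carbon nanoparticle arrays (triangles), with bars at group means and open symbols where neither array of the group was well above background. OsMADS6 had a mean of -7.23 on the control and 4.46 on the treated arrays, while GS2 had 5.74 and 1.52.

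The floral organ identity list, fixed as a marker of other tissue, had a median log2 difference of 6.88, or 5.45 with the genes below background at their bound (camera adjusted p = 1.13e-06, and adjusted p = 0.633 with an estimated correlation). Its 11 rises were the same number when adjusted over the list alone. OsMADS4, a PISTILLATA-like gene of petal and stamen identity, was well above background on 1 control array and both treated arrays and had a mean of 3.51 ± 0.70 (SD, n = 2) on the treated arrays. OsMADS16 was measured on all 4 arrays and rose by 3.24 ± 0.76 (adjusted p = 0.0342), a call lost without carbon nanoparticle replicate 1 or 2 (adjusted p = 0.0826 and 0.150) and under spike-in scaling (0.0685). The exception was DL, which is also active in leaf midribs, with a difference of -0.10 ± 0.45 (adjusted p = 0.890) whose sign turned under quantile normalisation and under 75th percentile scaling over detected probes. The pollen and anther list had 12 of 27 genes higher and 1 lower, also when adjusted over the list alone, with a median of 1.37 (camera adjusted p = 0.00242, and adjusted p = 0.633 with an estimated correlation). Its members included a gene similar to RAFTIN1a of the anther (Os08g0496800), at least 284-fold higher, Wda1, needed for anther wax, at least 165-fold higher, and the pollen kinase partner gene Os05g0454200, which rose by 5.55 ± 0.31. Without carbon nanoparticle replicates 1 and 2 in turn, the limits were 496-fold and 162-fold for Os08g0496800 and 287-fold and 95.0-fold for Wda1. The pollen median was 0.65 without control replicate 1, 2.53 without control replicate 2 and 2.12 without carbon nanoparticle replicate 2. With only probes well above background on all 4 arrays, the floral median was 3.24 and the pollen median 0.15. This filter leaves out genes absent from the controls, and neither list passed the test with it (adjusted p = 0.172 and 0.383). Only 3 of the 12 floral genes were well above background on both control arrays, so this floral result rests on few genes and decides little. With normexp correction the floral and pollen medians were 3.43 and 0.65, and under spike-in scaling the pollen median was 0.44. Without a filter on background the pollen median was 0.60 relative to all genes, against 1.39 with it.

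The list of cell cycle and histone genes had 35 of 95 members higher and 1 lower, and 43 and 2 when adjusted over the list alone. Its median was 1.02 (camera adjusted p = 2.78e-05, and adjusted p = 0.633 with an estimated correlation), and the median was 0.08 under spike-in scaling, 0.60 with normexp correction and 0.61 with median scaling. Without a filter on background the median was 0.33 relative to all genes, against 1.03 with it. This list and the floral list, whose median was 6.88, were both higher in the same single contrast, so their covariation was not measured. The kinesin gene Os03g0301800 rose by 5.20 ± 0.36 and the cyclin-dependent kinase inhibitor gene Os09g0459900 rose by 4.56 ± 0.35. The list was drawn by description words, which also match cyclin-dependent kinases, their inhibitors and every kinesin. It is thus not a strict marker of dividing cells. Cell wall expansion genes were higher for 40 of 60 and lower for 2, and 41 and 4 when adjusted over the list alone, with a median of 2.57 (camera adjusted p = 2.94e-09, and adjusted p = 0.633 with an estimated correlation). That median was 1.46 with normexp correction, 0.99 without a filter on background, or 0.53 relative to all genes against 2.59, and 1.64 under spike-in scaling. The xyloglucan-modifying enzyme genes Os04g0631200 and Os03g0108300 were higher by 6.81 ± 0.30 on the log2 scale and by at least 245-fold.

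Of 72 class III peroxidase genes 39 rose and 7 fell, and 41 and 8 when adjusted over the list alone (median 2.27, camera adjusted p = 6.23e-06, and adjusted p = 0.633 with an estimated correlation). Os04g0498700 was at least 124-fold higher and Os07g0677400 at least 72.1-fold lower. Of 55 phenylpropanoid and lignin genes 22 rose and 5 fell, and 26 and 6 when adjusted over the list alone (median 1.40, camera adjusted p = 0.000956, and adjusted p = 0.633 with an estimated correlation). The laccase gene Os05g0458600, of a family that polymerises lignin, was at least 546-fold higher, and the caffeoyl-CoA methyltransferase gene Os08g0498600 at least 45.1-fold higher. Of 95 auxin response genes 31 rose and 8 fell, and 32 and 8 when adjusted over the list alone, with a median of 0.80 that was -0.14 under spike-in scaling, or 0.81 relative to all genes (camera adjusted p = 0.00599, and adjusted p = 0.663 with an estimated correlation). The SAUR gene Os08g0452500 rose by 5.74 ± 0.34 and the GH3 gene Os01g0785400 was at least 36.8-fold higher. The peroxidase median was 0.79 with normexp correction, 0.93 without a filter and 1.33 under spike-in scaling. Relative to all genes, the medians without a filter were 0.47 for peroxidases, 0.32 for phenylpropanoids and 0.19 for auxin. With the filter they were 2.28, 1.41 and 0.81. The phenylpropanoid median was 0.61 with normexp correction, 0.79 without a filter, 0.46 under spike-in scaling, 0.55 with all 4 arrays above background and 0.92 without control replicate 1. The auxin median was 0.51 with normexp correction and 0.39 with median scaling. The phenylpropanoid list did not pass with all 4 arrays above background (adjusted p = 0.124), nor the auxin list without a filter (0.0628). These 3 lists, too, were higher in the same contrast as the floral markers, and covariation was not measured.

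The Calvin cycle list had a median of -3.65, or -3.21 with bounds, with 8 of 10 genes lower and all 10 lower when adjusted over the list alone (camera adjusted p = 1.57e-05, and adjusted p = 0.633 with an estimated correlation). The phosphoribulokinase gene Os02g0698000 fell by 5.03 ± 0.41 and the sedoheptulose bisphosphatase gene Os04g0234600 fell by 4.26 ± 0.57. The photosystem and light harvesting list had a median of -1.36, with 38 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.08e-10, and adjusted p = 0.633 with an estimated correlation). The PsbS gene Os01g0869800, whose product dissipates excess light, fell by 4.90 ± 0.40 and the Psb28 gene Os01g0938100 fell by 4.34 ± 0.41. Of 16 genes of chlorophyll and tetrapyrrole synthesis 10 fell, also when adjusted over the list alone (median -1.65, camera adjusted p = 0.000155, and adjusted p = 0.633 with an estimated correlation). Among them the magnesium chelatase gene Os03g0323200 fell by 3.12 ± 0.41 and the protochlorophyllide reductase gene Os10g0496900 fell by 2.95 ± 0.42, a call lost without carbon nanoparticle replicate 2 (adjusted p = 0.0543). Of 50 organellar ribosomal protein genes 24 fell, also when adjusted over the list alone (median -1.14, camera adjusted p = 5.59e-06, and adjusted p = 0.633 with an estimated correlation), with Os03g0265400 falling by 2.73 ± 0.32. Under spike-in scaling the medians were -2.29 for photosystems, -2.59 for tetrapyrrole synthesis and -2.08 for organellar ribosomes. In the same contrast the floral markers were higher, at a median of 6.88, and their covariation with these lists was not measured.

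**Figure D2:**
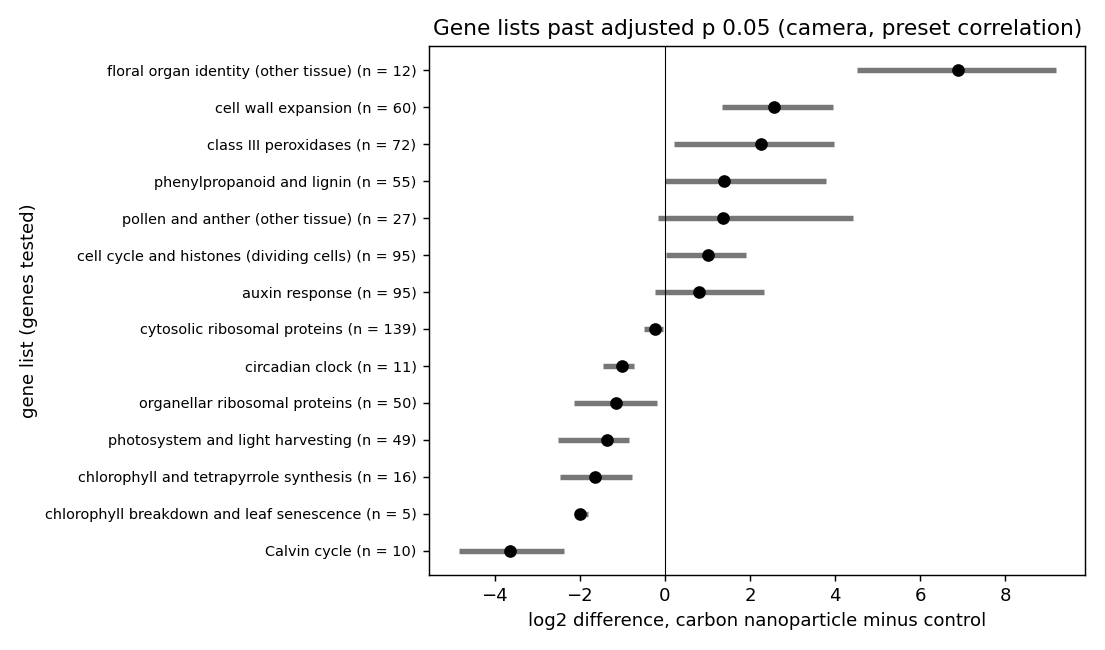
Median (points) and quartiles (bars) of the log2 difference, carbon nanoparticle minus control (x axis), over the tested members of the 14 gene lists past adjusted p 0.05 (y axis). Medians ran from -3.65 for the Calvin cycle to 6.88 for floral organ identity, and that of auxin response turned to -0.14 under spike-in scaling, which moved all genes alike, but was 0.81 relative to all genes and the list still passed in the higher direction (adjusted p = 0.00110).

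Of the 5 chlorophyll breakdown genes tested 4 fell, also when adjusted over the list alone (median -1.98, camera adjusted p = 0.0249, adjusted p = 0.633 with an estimated correlation and 0.0928 with the scan as a block, and 0.103 without control replicate 1), and the median was -0.98 with normexp correction. The list missed the threshold under median and spike-in scaling (0.0513 and 0.0556). NYC3 fell by 2.70 ± 0.36 and PAO, which opens the chlorophyll ring, fell by 2.06 ± 0.34. Without carbon nanoparticle replicate 2 neither passed (adjusted p = 0.0516 for NYC3 and 0.0866 for PAO), nor did PAO without replicate 1 (0.0611). Of 11 circadian clock genes 5 fell, also when adjusted over the list alone (median -0.995, camera adjusted p = 0.0104, adjusted p = 0.633 with an estimated correlation and 0.0651 without control replicate 2), and the median was -1.93 under spike-in scaling. OsLUX fell by 3.35 ± 0.44 and OsPRR37 fell by 2.26 ± 0.40 (adjusted p = 0.0846 and 0.0688 without carbon nanoparticle replicate 1 or 2), whereas OsGI and OsLHY had differences of -0.92 ± 0.50 and -0.59 ± 0.58 that did not pass (adjusted p = 0.242 and 0.508). Of 139 cytosolic ribosomal protein genes 3 fell and 1 rose, and none when adjusted over the list alone. Their median was -0.24, but -0.09 with quantile normalisation, -0.65 with median scaling, -0.44 with no scaling, -1.18 with spike-in scaling, -0.13 with the percentile over detected probes, -0.05 without control replicate 1, -0.45 without control replicate 2 and -0.16 without carbon nanoparticle replicate 1 (camera adjusted p = 0.0286, adjusted p = 0.915 with an estimated correlation and 0.693 with the scan as a block, 0.730 without control replicate 1 and 0.0524 without carbon nanoparticle replicate 1), and the list did not pass with quantile normalisation (0.475), the percentile over detected probes (0.0677) or all 4 arrays above background (0.0735). Between the same groups the floral markers were higher, at a median of 6.88, and their covariation with these 3 lists was not measured.

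With the scan as a block, the list medians were 6.35 for floral organ identity, 2.18 for cell wall expansion, 1.86 for peroxidases, 1.02 for phenylpropanoids, 0.92 for the cell cycle, 0.65 for pollen and 0.59 for auxin, and -3.47 for the Calvin cycle, -1.94 for tetrapyrroles, -1.57 for photosystems, -1.30 for the clock and -1.27 for organellar ribosomes. Control replicate 1 was the only array of its scan, so this fit sets control replicate 2 alone against both treated arrays. It is the same contrast as the comparison within the shared scan, not a second check.

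The flowering and photoperiod list did not pass the test (median -0.89, adjusted p = 0.0922), with 5 of 15 genes lower, and 6 lower and 2 higher when adjusted over the list alone. Hd3a, a mobile flowering signal, and the repressor Ghd7 were not well above background on any array, and Ehd1 was above it with 1 probe on control replicate 2 alone. Hd1 had a difference of 0.32 ± 0.42 (adjusted p = 0.627) whose sign turned under spike-in, median and quantile scaling. PHYB, a red light receptor, had one of -0.89 ± 0.34 (adjusted p = 0.120). OsMADS14 and OsMADS18, which act at the transition to flowering, fell by 1.89 ± 0.35 and 1.41 ± 0.30 (adjusted p = 0.0180 and 0.0252). The call of OsMADS18 was lost without any 1 of the 4 arrays (adjusted p from 0.0664 to 0.204) and with the scan as a block (0.0683), and that of OsMADS14 without control replicate 2 or either treated replicate (0.0555, 0.0874 and 0.104).

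The nitrogen list also missed the threshold (median -2.24, or -1.98 with bounds, adjusted p = 0.0523), with 7 of 13 genes lower and 1 higher, and 7 and 3 when adjusted over the list alone. GS2 and Fd-GOGAT, which assimilate ammonium in the chloroplast, fell by 4.23 ± 0.43 and 3.52 ± 0.30. The ammonium transporter gene AMT1;1 fell by 3.63 ± 0.33 and the nitrate transporter gene NRT2.3 rose by 3.33 ± 0.39. Of 10 antioxidant enzyme genes 1 fell, also when adjusted over the list alone (list adjusted p = 0.533). It was the leaf catalase gene CATC, which fell by 6.27 ± 0.37.

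The remaining lists did not pass the test, and counts in brackets are higher and lower calls, first over all genes and then adjusted over the list alone. Among hormone lists these were gibberellin (5 and 2, 5 and 4; adjusted p = 0.815), cytokinin (2 and 2, 2 and 2; 0.707), ethylene (6 and 0, 4 and 0; 0.396) and jasmonate (4 and 3, 3 and 3; 0.903). Among stress and defence lists these were drought, salt and abscisic acid (1 and 0, 1 and 0; 0.875), late embryogenesis abundant proteins (8 and 1, 8 and 1; 0.533), heat shock proteins (18 and 15, 18 and 14; 0.501), glutathione S-transferases (8 and 9, 10 and 14; 0.2998), defence and phytoalexins (2 and 1, 2 and 2; 0.856), pathogenesis-related proteins (20 and 7, 23 and 11; 0.140), disease resistance proteins (25 and 14, 26 and 14; 0.501), receptor-like kinases (17 and 18, 20 and 20; 0.875), cytochrome P450 (24 and 31, 31 and 35; 0.780) and terpene synthesis (0 and 1, 0 and 1; 0.533). The WRKY (6 and 5, 6 and 5; 0.815) and NAC factors (11 and 6, 11 and 8; 0.856) did not pass either. Nor did transport and nutrient lists, namely iron (1 and 2, 1 and 2; 0.903), metal transport (15 and 9, 18 and 11; 0.513), aquaporins (0 and 1, 0 and 1; 0.786), sugar transport (3 and 6, 3 and 6; 0.396), nitrate and peptide transport (5 and 10, 6 and 11; 0.118) and phosphate (4 and 7, 4 and 7; 0.429). The same held for sucrose and starch (6 and 4, 6 and 4; 0.903), yield and architecture (5 and 1, 5 and 1; 0.193), seed storage proteins (3 and 2, 3 and 3; 0.610) and transposons (1 and 1, 1 and 1; 0.635). Median, mean and test differed in sign for 8 of these lists, namely iron, heat shock, receptor-like kinases, cytochrome P450, gibberellin, cytokinin, aquaporins and transposons.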

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

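Both tests in this part were chosen only after the result was seen. The spike-in control probes, which report RNA added during labelling and served here only for spike-in scaling, were brighter on the treated than on the control arrays by 0.74 on the log2 scale, over the 5 probes well above background throughout. Their mean log2 levels were 8.22 and 7.62 on the control and 8.80 and 8.52 on the treated arrays. The separate scan of control replicate 1 is argued against as the whole cause, because the lower treated array exceeded the control array of the same scan by 0.91. A smaller share of labelled rice RNA on the treated arrays would lower total rice signal there, which was at most 84.8% of the lower control total. The brightest probes weigh most in that total, and the highest signal was 20351 and 18477 on the treated against 68424 and 65186 on the control arrays. The 75th percentile was 186 and 155 against 199 and 189, and the median 18.0 and 14.5 against 14.7 and 13.1. The total therefore does not decide whether the share of rice RNA was smaller. Unequal addition of spike-in RNA was not tested, nor was a biological explanation, and with 2 arrays per group these stay open.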

How the results depend on the processing

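The signal over background limited the sizes of differences, since 1052 genes called higher and 557 called lower were below background on both arrays of the other group. It also bore on list calls. Of the 14 called lists, 4 lost their call with all 4 arrays above background, and 1 did without a filter. Scaling moved the median difference of all genes from -0.01 to -0.42 with the array median, -0.21 with no scaling and -0.95 with spike-in probes. Under spike-in scaling the list medians were -0.14 for auxin, 0.08 for the cell cycle, 0.44 for pollen and 0.46 for phenylpropanoids, or 0.81, 1.03, 1.39 and 1.41 relative to all genes. Spike-in scaling gave 2284 genes higher and 6199 lower, and of the original calls 2276 and 2570 were kept. Requiring all 4 arrays above background gave 2457 higher, with fewer genes tested, and every probe as its own feature gave 4481 lower and 12880 past the looser threshold, with more features tested. Normexp correction gave 4940 genes past the looser threshold. The lowest correlation within groups exceeded the highest between groups by 0.247, and by 0.183 with normexp, 0.0748 without a filter, 0.172 with all 4 arrays above background and 0.279 with the mean of probes. The cause was not tested for normexp, spike-in scaling or the mean of probes. Leaving out each array, where a lone sample is assumed to vary like the other group, gave 2163 to 3085 genes higher, 1006 to 2104 lower, 6895 to 8903 past the looser threshold, 13 to 16 lists and a gap of 0.230 to 0.262. With an estimated correlation 0 lists were called, against 14. That estimate rests on 2 residual degrees of freedom, and its lowest unadjusted p over all lists was 0.0416. It could therefore hardly call any list, and the 0 calls decide little. Of the genes called, 20 turned sign with normexp, and 1 each with all 4 arrays above background, with the mean of probes and without carbon nanoparticle replicate 2. The named genes that turned sign had not passed the test. For DL they were 0.0040 with quantile normalisation, 0.0043 with the percentile over detected probes, 0.22 with the scan block, and from -0.51 to 0.31 over the left-out arrays. For Hd1 they were -0.0757 with quantile normalisation, -0.0926 with median scaling, -0.62 with spike-in scaling and from -0.15 to 0.78 over the left-out arrays. For OsLHY they ran from -1.35 to 0.18 over the left-out arrays. Over all alternatives the named genes kept direction and side of the threshold in 1250 comparisons, lost a call in 18 and gained one in 1. The called lists kept theirs in 261 and lost it in 33. Of the 261, 14 under another variance model were fixed in advance, since the list test does not use that model. The value table repeats the main values apart from its floor, so its 69 gene and 14 list comparisons add little. Named genes were largely picked for large differences or small p in these same data, and the lists for passing. This stability is thus not independent support. The scan block repeats the contrast without control replicate 1, so those comparisons are not separate. The replicate numbers did not establish pairing, as the deviations of same-numbered arrays correlated at 0.131 over only 2 pairs, and with a replicate block 3808 genes were higher and 2537 lower, 8670 passed the looser threshold and 15 lists were called. A slide block was not run because the arrays lay on 1 slide.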

Other observations

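The words of the gene descriptions were counted among the calls after the list results were seen, for all 480 words found in at least 15 tested genes. Hypergeometric tests were adjusted over words and directions. They treat genes as independent draws, though all calls come from the same 4 arrays, so these p-values reflect numbers of genes and not replication. Over all 22111 genes tested, 3810 were called higher and 2570 lower. Genes of fasciclin-type (FAS1) adhesion proteins rose in 15 of 17 cases and none fell (adjusted p = 5.25e-08, median log2 difference 5.40). Pectin-related genes rose in 19 of 27 cases (adjusted p = 1.92e-07), GDSL lipase genes in 22 of 36 (4.08e-07) and cupredoxin genes, which bind copper, in 18 of 31 (1.97e-05). Genes described with the word chloroplast fell in 95 of 204 cases and rose in 7 (adjusted p = 7.39e-33). Genes of pentatricopeptide proteins, which process organelle transcripts, fell in 38 of 163 cases and rose in 2 (adjusted p = 0.000571).

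Among 9 iron genes, some differed widely between arrays of the same group, which was not tested. NAS1 and NAS2, which make the metal chelator nicotianamine, were higher on control replicate 2 than on replicate 1 by 5.53 and 5.71 on the log2 scale, and higher on carbon nanoparticle replicate 2 than on replicate 1 by 3.36 and 2.65. The transporter gene YSL2 differed by 3.58 between the control arrays and 0.14 between the treated ones. In the controls the gaps of the other genes were 1.61 for YSL15, 1.22 for IRT1, 0.86 for IRO2, 0.50 for FER2, 0.31 for FER1 and -0.51 for NAS3. Of 22105 genes, 95 (0.430%) differed by at least 16-fold between those arrays.

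The tests of a mislabelled array, of unfiltered probes, of other splits of the arrays, of the dilution of leaf RNA and of the scaling factors were chosen only after the result was seen. Floral organ identity genes were higher on both treated arrays, 6 of the 12 being below background on both control arrays and 3 above it on both. The scan is argued against by a median difference of 6.35 within the shared scan. A single mislabelled array is argued against by a lowest within-group correlation of 0.946, against 0.700 between groups. Cross-hybridisation of single probes is argued against by the other probes of these genes, of which 24 of 25 (96%) were higher by over 1 on the log2 scale. The 100% among the 24 that passed the filter decides nothing, since the filter dropped the only probe that did not rise so far. The real grouping called 6380 genes and the highest other split 0, with 1 of 3 splits as large, too few for a share under 0.05. RNA of panicle or flower tissue in the treated samples is a candidate explanation that the labels, which name flag leaves, do not give. The pollen and anther list, at 1.37, rose with cell cycle and histone genes while photosystem genes fell, as it would need. These list calls used the preset correlation, and none held with an estimated one. The pollen median was 0.65 without control replicate 1. It was 0.15 with only probes above background on all 4 arrays, which leaves out genes absent from the controls. A response of leaf cells to the nanoparticles stays open as untested, since all treated samples share both, as does a swap of whole samples with outside ones.

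Many genes detected in the controls were much lower on both treated arrays. Another tissue's RNA added to leaf RNA, up to an equal share, allows falls of about 2-fold. It is argued against, since 1563 of the 22111 genes tested were called lower by at least 4-fold. They made up 60.8% of the genes called lower. That share is raised by the calling, since in simulation 4-fold changes were called more often than 2-fold ones. Scaling between arrays is argued against, since the factors applied to a control and a treated array differed by at most 0.36 on the log2 scale and a factor moves all genes of an array alike, while 1563 genes were lower and 2693 higher by at least 4-fold. That 100% of those 1563 genes stayed lower by over 2-fold under 4 other scalings decides nothing, because none of the 5 scalings tried moved the treated arrays up by over 0.11. A larger share of other tissue, or its use in place of flag leaf, may remain, as does a response to treatment.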
